A study of Rattus norvegicus with 9 samples.

How the data were processed

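RNA was measured in dorsal root ganglia of male Sprague-Dawley rats in 9 libraries, 3 each from naive, sham-operated and SCI animals. Per the labels' protocols, total RNA was extracted with the RNeasy Mini Kit and paired-end libraries were made with the TruSeq RNA Sample Prep Kit V2, which does not mark strand. Reads from a gene and an overlapping antisense gene therefore cannot be told apart. Per the submitters' processing notes, FastQC, Trimmomatic, TopHat2, HTSeq and DESeq2 were used. Their versions and the genome build and annotation are not given in the sources used here. The values deposited by the authors are whole-number counts of reads per gene, not normalized, for 30446 genes (24807 with an Ensembl identifier and 5639 with another). Library totals ran from 16724878 to 32060538 counts, so that a gene at 1 CPM rests on about 16.7 to 32.1 counts, and counting error adds to the spread of genes at that level. All count columns were used.

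Gene symbols were taken from the deposited table. Several identifiers can share a symbol (348 symbols, 723 identifiers), and reads of near-identical gene copies, such as ribosomal proteins and their pseudogenes, may be split between them, so single ribosomal protein values are uncertain. For the gene lists, older symbols were matched through a RefSeq gene table of assembly GRCr8, used for names only. Of 862 listed symbols, 812 matched and 760 genes were tested, and the others were not analysed here. No sequence reference was used, so GC content and measured gene length were not analysed here. Length enters only through a hand-written list of 51 genes known for very long coding sequences, of which 44 were tested.

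Each sample's group was taken from its treatment label. The main test was edgeR's quasi-likelihood test (version 4.0.16, in R 4.3.3) on the counts as deposited, with TMM scaling, the default low-count filter by group, 1 mean per group and all 9 libraries in 1 fit (6 residual degrees of freedom), and Benjamini-Hochberg adjustment, with calls at an adjusted p under 0.05. Log2 changes and standard errors come from that fit. The comparisons were SCI against sham, SCI against naive, sham against naive, SCI against the mean of both control groups, and any difference among the 3 groups. CPM were computed from TMM-scaled library sizes, and log2 CPM used a prior count of 2.

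The groups, comparisons, 41 gene lists, naming rule and most alternatives were fixed before the data were examined. Of the 41 lists of cell types, pathways and neuronal functions, 40 had at least 5 tested members. They were tested with limma's camera (version 3.58.1) at a preset correlation of 0.01, and again with an estimated correlation and with fry, which tests whether a list's genes move, on balance, one way and does not compare the list with other genes. Members were also counted after adjustment over the list alone. Named genes were, for each of the first 3 comparisons, the 10 higher and the 10 lower with the smallest p among called genes whose groups do not overlap. Where fewer than 5 genes passed, the 5 with the smallest p were named as not passing. Up to 4 members of each called list in its direction were added, and for SCI against sham the 4 members with the smallest p of 6 lists (axon injury, peptidergic and nonpeptidergic nociceptors, macrophage, satellite glia and cAMP signaling). Loci without a proper symbol were passed over, and some genes that the rule takes are not reported here. For SCI against both control groups, and for genes that another test or filter called between SCI and sham (Tnnc2, Wsb1, Ckm and Mb), genes were named after their values were seen.

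The same replicate numbers occur in all groups, and the labels do not say that they mark shared animals or days. The alternatives were RLE and upper-quartile scaling, no filter and a strict filter, DESeq2 (version 1.42.0), limma-voom, a robust spread, only the groups compared, the replicate number as a block, each library left out in turn, an adjusted p under 0.1 and a fold of at least 1.5. After seeing the data, 3 were added: the level of the skeletal muscle list as a covariate, thinning of all libraries to the shallowest total, and lists without single members. The test was checked on simulated counts for SCI against sham with the real means, spreads and library sizes and 200 changed genes per run over 5 runs on 16461 genes. It found 19.6% of genes changed 1.25-fold, 64.4% of those changed 1.5-fold, 83.2% of those changed 2-fold and 95.6% of those changed 4-fold, with 10.6 false calls per run. A list shifted by 0.5 on the log2 scale was called in 5 of 5 runs. Genes were drawn independently and with the same spread in all groups. The simulated counts thus lack the correlation between genes and the wider spread of the sham libraries, and these rates may not hold for the real data. For comparisons that share libraries, 40 simulated sets of unchanged groups were drawn.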

Results

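Messenger RNA was sequenced from dorsal root ganglia (DRG), the clusters of sensory neuron cell bodies and their glia beside the spinal cord, of male Sprague-Dawley rats. Ganglia from the lowest thoracic to the sixth lumbar level of both sides were taken at 30 days. The 9 libraries form 3 groups of 3: naive rats, rats with a sham operation and rats with a spinal cord injury (SCI). The labels do not state whether each library came from 1 animal or a pool, so p-values measure the spread between these libraries. Library totals were 27534798, 31816438 and 30816850 counts for naive libraries 1 to 3, 28026976, 16724878 and 20199518 for sham libraries 1 to 3, and 32060538, 20168733 and 22024200 for SCI libraries 1 to 3. Of 30446 genes in the table, 16627 passed the low-count filter and were tested. The spread between libraries of a group corresponded to a square root of the common dispersion of 0.0805. Levels are given as CPM, counts scaled to library size, as mean ± SD with n = 3 in every group.

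The naive libraries lay apart from all others on the first principal component of log2 CPM, which held 59.3% of the variance. Their scores ran from -43.5 to -41.6, and those of the sham and SCI libraries from 14.2 to 25.7. The second component held 11.2% and spread the sham libraries, with sham 1 at -25.9 and sham 3 at 26.2, while the SCI libraries lay between 1.63 and 6.60. Within groups, the correlation of log2 CPM was lowest for sham 1 with sham 3, at 0.988, and highest for naive 2 with naive 3, at 0.996. Every pair of libraries differed by more than sampling noise, with a chi-square per degree of freedom of 3.78 to 5.08 between naive libraries, 12.6 to 40.1 between sham libraries and 3.05 to 7.82 between SCI libraries. The values of sham 2 with the SCI libraries (4.14 to 7.12) lay below those with sham 1 and sham 3 (12.8 and 12.6).

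**Figure D1:**
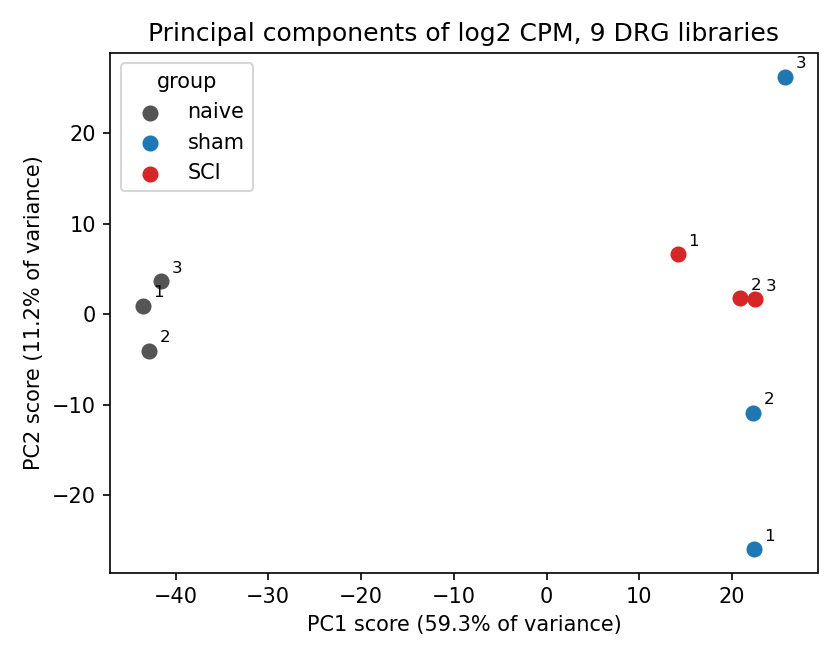
Scores of the 9 libraries on the first (x axis, 59.3% of variance) and second (y axis, 11.2% of variance) principal components of log2 CPM. Each point is 1 library, coloured by group and numbered by replicate, and the 3 naive libraries lie at -41.6 or below on the first component while all others lie at 14.2 or above.

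The comparison of SCI with sham asked which transcripts in the ganglia differed after cord injury beyond the effect of the operation. Genes of skeletal muscle lay lower in SCI, and genes linked to axon injury and immediate early genes lay higher, each as a list. No single gene passed an adjusted p of 0.05 in edgeR, while DESeq2 called 8. With an estimated correlation between genes these list calls were lost (adjusted p = 0.0844, 0.0832 and 0.841). Vip, which encodes a neuropeptide known to rise in sensory neurons after axotomy, stood at 3.21 ± 0.591 CPM in SCI, 1.09 ± 0.609 in sham and 0.413 ± 0.167 in naive (log2 change SCI against sham 1.63, SE 0.31, edgeR adjusted p = 0.442). Fos, an activity-induced transcription factor, stood at 11.9 ± 0.746 CPM in SCI, 7.05 ± 1.54 in sham and 6.87 ± 0.992 in naive (log2 change 0.76, SE 0.15, edgeR adjusted p = 0.495). The lowest SCI library lay above the highest sham library for both genes.

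Among the 5 genes with the smallest p in this comparison, none of which passed in edgeR, 4 encode parts of the striated muscle sarcomere. Acta1, skeletal muscle actin, stood at 29.0 ± 5.28 CPM in SCI against 49.4 ± 7.46 in sham and 20.4 to 29.3 in the naive libraries (log2 change -0.77, SE 0.15). Tnni2 and Tnnt3, fast-twitch troponins, had log2 changes of -1.11 (SE 0.20) and -0.73 (SE 0.14). Myoz1, a Z-disc protein, had a log2 change of -1.29 (SE 0.22). These 4 genes and Vip all had an edgeR adjusted p of 0.442, and in all 5 the SCI and sham libraries did not overlap. With the level of the skeletal muscle list as a covariate, which takes up the list's mean change by construction, Myoz1, Tnni2, Acta1 and Tnnt3 had log2 changes of -0.62, -0.26, 0.079 and 0.047. DESeq2 called all 5 (adjusted p = 0.0274 for Myoz1, 0.0137 for Tnni2 and Acta1, 0.0196 for Tnnt3 and 0.0370 for Vip), and edgeR without a low-count filter called them as well.

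The edgeR quasi-likelihood test called 0 of 16627 genes between SCI and sham. At an unadjusted p under 0.05 there were 526 genes with edgeR, against 831 that chance would give, but 2329 without sham 3 and 1057 without sham 1. The libraries of both groups did not overlap in 6.41% of genes, where chance gives 10%. DESeq2 called 8 genes (3 higher, 5 lower), which were those 5, Fos, Tnnc2 and Wsb1, at adjusted p from 0.0137 to 0.0386. Limma-voom called 0, and edgeR without a low-count filter 11 (4 higher, 7 lower). Without sham 3, edgeR called 22 genes (19 higher, 3 lower).

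Of 40 gene lists tested by a competitive list test (camera with a preset correlation of 0.01), 7 were called between SCI and sham, 2 higher and 5 lower. The skeletal muscle list fell, with a negative log2 change in all 18 measured members and a median of -0.75 (camera adjusted p = 8.07e-27). In edgeR none of its members passed over all genes tested and 16 passed when adjusted over the list alone, while DESeq2 called Tnni2, Acta1, Tnnt3, Myoz1 and Tnnc2, and edgeR without a filter these and Ckm and Mb. With an estimated correlation the adjusted p was 0.0844. One member, Pvalb, is also abundant in proprioceptive sensory neurons, and without it the median was -0.77 in the remaining 17 genes. Summed over the list, the muscle genes made up 306 ± 22.3 CPM in SCI, 406 ± 8.39 in sham and 221 ± 24.7 in naive, of which Pvalb alone made up 196 ± 5.35, 219 ± 17.9 and 107 ± 2.80.

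The axon injury and regeneration list rose, with 20 of 22 members positive and a median log2 change of 0.17 (camera adjusted p = 2.65e-05; adjusted p = 0.0832 with an estimated correlation). In edgeR none of its members passed over all genes and 1 passed adjusted over the list alone, while Vip was called by DESeq2 and without a filter. Reg3b, a secreted lectin induced in injured sensory neurons, had a log2 change of 2.03 (SE 0.62) and did not pass, and SCI 3 held 8.69 CPM where the SCI mean was 3.97 ± 4.10. Without Reg3b the list had a median of 0.16 (camera adjusted p = 0.000122). Stmn4, a microtubule regulator, and Gal, the neuropeptide galanin, had log2 changes of 0.19 (SE 0.08) and 0.25 (SE 0.13), neither of which passed. The immediate early gene list rose as well, with 18 of 23 members positive and a median of 0.15 (camera adjusted p = 2.24e-05; adjusted p = 0.841 with an estimated correlation). Its mean log2 CPM was 3.76 in naive, 3.63 in sham and 3.83 in SCI. Between SCI and naive the list was not called (median 0.052, camera adjusted p = 0.708). As a list, these genes thus lay above sham in SCI but near their naive level. In edgeR 2 of its members passed adjusted over the list alone and 0 over all genes, while Fos was called by DESeq2, without a filter and without sham 3, and Fosb without a filter. Fosb stood at 3.58 ± 1.94 CPM in SCI (2.10, 2.87 and 5.78 in SCI 1 to 3) and 1.28 ± 0.273 in sham. Egr1 stood at 29.2 ± 3.51 and 23.4 ± 4.16, and neither Fosb nor Egr1 passed in edgeR with the main filter.

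The nuclear-encoded oxidative phosphorylation list had 1 of 38 members positive and a median log2 change of -0.07 (camera adjusted p = 2.24e-05; adjusted p = 0.841 with an estimated correlation), with Cox4i1 at -0.14 (SE 0.07) and Cox6a1 at -0.14 (SE 0.08). The endoplasmic reticulum stress list had 1 of 19 members positive and a median of -0.06 (camera adjusted p = 0.00280; adjusted p = 0.888 with an estimated correlation), with Ddit3, a stress-induced transcription factor, at -0.19 (SE 0.08). The pericyte and smooth muscle list had a median of -0.16 over 14 genes (camera adjusted p = 0.0137; adjusted p = 0.990 with an estimated correlation), with Actg2 at -0.45 (SE 0.17) and Cnn1 at -0.29 (SE 0.15). The potassium channel list had 4 of 33 members positive and a median of -0.06 (camera adjusted p = 0.0159; adjusted p = 0.990 with an estimated correlation), with Kcnn2, a calcium-activated channel, at -0.28 (SE 0.12). No member named from these lists passed in edgeR. The hand-written list of genes with very long coding sequences lay slightly higher in SCI than in sham, with 33 of 44 members positive and none called. Its median of 0.043 lay at or above 99.97% of 10000 random lists of like expression. Whether the small changes of the lists above share a source with it was not tested. The call of the potassium channel list was lost without sham 1 (median 0.011, camera adjusted p = 0.299), sham 2 (-0.067, camera adjusted p = 0.0588), SCI 1 (-0.050, 0.0587) or SCI 3 (-0.057, 0.198). That of the pericyte list was lost without sham 3 (median -0.013, camera adjusted p = 0.797), SCI 2 (-0.092, 0.0518) or SCI 3 (-0.133, 0.0610). At equal depth it was lost as well, with a median of -0.168 (camera adjusted p = 0.127). That of the endoplasmic reticulum stress list was lost without sham 2 (median -0.032, camera adjusted p = 0.102) or SCI 3 (-0.037, 0.104). The count of called lists was 24 without sham 3 and 14 without sham 1, and 8 of the 10 divisions of the SCI and sham libraries into 3 and 3 called 7 or more. With the level of the skeletal muscle list as a covariate, which itself parts SCI from sham and was chosen after seeing the data, the oxidative phosphorylation list had a median of 0.015 (camera adjusted p = 0.898) and the potassium channel list -0.013 (camera adjusted p = 0.660).

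Lists of sensory neuron classes, glia and immune cells were not called between SCI and sham. The peptidergic nociceptor list had a median log2 change of -0.05 over 11 genes (camera adjusted p = 0.718), and its members Tac1, Calca and Calcb, which encode substance P and the calcitonin gene-related peptides, had log2 changes of -0.14 (SE 0.09), -0.12 (SE 0.09) and -0.12 (SE 0.09), which turned to 0.23, 0.19 and 0.25 with the level of the skeletal muscle list as a covariate. The nonpeptidergic nociceptor and pruriceptor list had a median of -0.01 over 18 genes (camera adjusted p = 0.971). Within it, Nppb, an itch neuropeptide, stood at 1.44 ± 0.386 CPM in SCI and 0.770 ± 0.223 in sham, and Mrgprd had a log2 change of -0.31 (SE 0.13), neither of which passed. The macrophage list had a median of 0.01 over 22 genes (camera adjusted p = 0.971), with Cd74 at 327 ± 16.5 CPM in SCI and 297 ± 39.6 in sham. The satellite glia list had a median of 0.07 over 16 genes (camera adjusted p = 0.0561), with Gfap at a log2 change of 0.38 (SE 0.13) and Ptgds, prostaglandin D2 synthase, at 0.38 (SE 0.14). Over the alternatives Gfap ranged from 0.021 to 0.565 and Ptgds from 0.225 to 0.559. The cAMP signaling list had a median of -0.02 over 31 genes while its test pointed up (camera adjusted p = 0.971), with Rapgef3 (Epac1) at 0.30 (SE 0.11), or -0.088 with that covariate, and Adcy8 at -0.20 (SE 0.10). None of the genes named from these lists passed in edgeR.

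**Figure D2:**
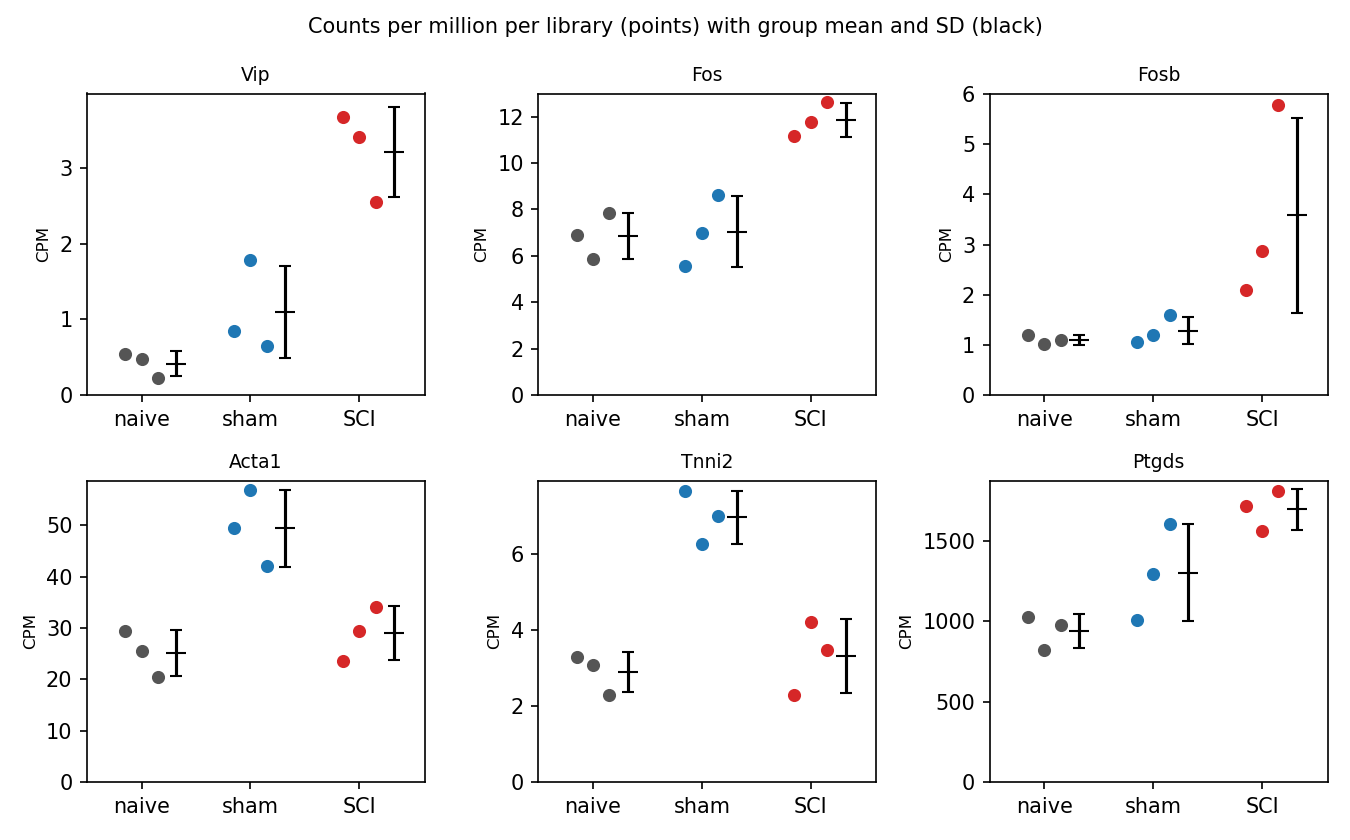
CPM (y axis, from 0) of 6 genes in each library (points), by group (x axis), with the group mean and SD in black. Vip, Fos and Fosb lie higher in all 3 SCI libraries than in all 3 sham libraries, Acta1 and Tnni2 lie lower, and Ptgds overlaps.

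The comparison of SCI with naive asked how ganglia after cord injury and surgery differed from those of unoperated rats. Genes of ribosomal proteins, oxidative phosphorylation and axon injury were higher in SCI, each as a list, and genes of Schwann cell myelin and cholesterol synthesis were lower. With an estimated correlation these list calls were lost (adjusted p = 0.681 for axon injury and 0.954 for the others). The naive libraries stand apart from both other groups, and the labels give no batch. An effect of injury or surgery can therefore not be told apart here from a batch that holds only the naive libraries. Stac2, which encodes an adaptor of voltage-gated calcium channels, rose from 0.807 ± 0.0901 CPM in naive to 4.84 ± 0.886 in SCI (log2 change 2.58, SE 0.19, edgeR adjusted p = 9.28e-07). In sham it stood at 2.98 ± 0.321 CPM. Igfbp2, an insulin-like growth factor binding protein, rose from 38.3 ± 3.49 to 76.7 ± 2.86 CPM (edgeR adjusted p = 6.56e-07). Usp9x, a deubiquitinase, fell from 568 ± 16.8 to 197 ± 10.5 CPM (log2 change -1.53, SE 0.07, edgeR adjusted p = 2.23e-08).

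The 10 genes with the smallest p among those higher in SCI than in naive were Lsm4, Hmga1, Igfbp2, Mrpl43, Anapc15, Hypk, Stac2, Hcfc1r1, Timm13 and Fabp5. Lsm4, of the spliceosome, had a log2 change of 0.97 (SE 0.06). Mrpl43, of the mitochondrial ribosome, and Timm13, of mitochondrial protein import, had log2 changes of 0.97 (SE 0.07) and 0.88 (SE 0.07). Fabp5, a fatty acid binding protein, rose from 223 ± 6.57 to 434 ± 22.6 CPM. Sham levels were like those of SCI for Fabp5 (444 ± 35.0 CPM) and Lsm4 (101 ± 5.80 in sham, 94.8 ± 3.17 in SCI). Such differences from naive are not particular to cord injury. The 10 among those lower included Usp9x, Herc1, Nfat5, Mycbp2, Dmxl2, Igf2r, Birc6, Slc12a2 and Herc2. The ubiquitin ligases Herc1, Mycbp2, Birc6 and Herc2 had log2 changes of -1.43, -1.38, -1.66 and -1.21. These proteins are very large, and of 44 further genes with very long coding sequences, a list written after the named genes were seen, 41 were called lower in SCI (median log2 change -0.90). Slc12a2, the chloride importer NKCC1, had a log2 change of -1.25 (SE 0.07).

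By gene list, 8 of 40 lists were called between SCI and naive, 5 higher and 3 lower, and none of them with an estimated correlation. The ribosomal protein list rose, with 37 of 40 members called higher and none lower (median log2 change 0.60, camera adjusted p = 1.69e-08; adjusted p = 0.954 with an estimated correlation). Rpl14 rose from 228 ± 3.18 to 443 ± 11.0 CPM, and adjusted over the list alone the same number, 37, passed. The oxidative phosphorylation list rose, with 28 of 38 members called higher (30 higher and 1 lower adjusted over the list alone) and a median of 0.30 (camera adjusted p = 3.94e-07; adjusted p = 0.954 with an estimated correlation). Cox5b and Ndufb8 had log2 changes of 0.83 (SE 0.08) and 0.71 (SE 0.07). The Schwann cell myelin list fell, with 16 of 20 members called lower and 1 higher (17 adjusted over the list alone), and a median of -0.55 (camera adjusted p = 0.000122; adjusted p = 0.954 with an estimated correlation). Pmp22, a compact myelin protein, fell from 6492 ± 225 to 3550 ± 325 CPM, and Mal and Gldn had log2 changes of -0.91 (SE 0.10) and -0.81 (SE 0.07).

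The cholesterol synthesis list fell, with 14 of 23 members lower and 4 higher (21 adjusted over the list alone) and a median of -0.22 (camera adjusted p = 0.0175; adjusted p = 0.954 with an estimated correlation). Its member Idi1 fell from 182 ± 2.95 to 113 ± 5.28 CPM (log2 change -0.69, SE 0.08). The GABA and glutamate receptor list fell, with 11 of 24 members lower and 1 higher (12 adjusted over the list alone) and a median of -0.31 (camera adjusted p = 0.0175; adjusted p = 0.954 with an estimated correlation). Its members Gria2 and Gabra2, an AMPA and a GABA receptor subunit, had log2 changes of -0.85 (SE 0.13) and -0.75 (SE 0.13), and its member with the smallest p, Slc12a2, is a chloride transporter and not a receptor. The axon injury and regeneration list rose, with 12 of 22 members higher and 2 lower (16 adjusted over the list alone) and a median of 0.34 (camera adjusted p = 0.0175; adjusted p = 0.681 with an estimated correlation). Within it, Vip had a log2 change of 2.97 (SE 0.34, edgeR adjusted p = 1.61e-05), Gal 0.88 (SE 0.13), Stmn4 0.73 (SE 0.08) and Gadd45a 0.40 (SE 0.06). The list's mean log2 CPM was 3.00 in naive, 3.17 in sham and 3.46 in SCI, and it was not called between sham and naive. Gal stood at 5.99, 9.33 and 11.0 CPM in naive, sham and SCI, and Stmn4 at 20.1, 29.3 and 33.4. Part of the difference from naive was thus present without cord injury. The skeletal muscle list was not called (median 0.07 over 18 genes, with 3 higher and 3 lower; 6 adjusted over the list alone; camera adjusted p = 0.708).

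The pericyte and smooth muscle list rose, with 8 of 14 members higher and 1 lower (10 adjusted over the list alone) and a median of 0.42 (camera adjusted p = 0.0175; adjusted p = 0.954 with an estimated correlation). Myl9 and Cnn1, of the contractile apparatus of smooth muscle, had log2 changes of 1.05 (SE 0.12) and 1.37 (SE 0.16). The interferon response and antigen presentation list rose, with 13 of 27 members higher and 1 lower (14 adjusted over the list alone) and a median of 0.31 (camera adjusted p = 0.0492; adjusted p = 0.954 with an estimated correlation). Cd74, the invariant chain of class II antigen presentation, and Isg15 had log2 changes of 0.85 (SE 0.11) and 0.73 (SE 0.13). The interferon list lost its call without naive 2 (camera adjusted p = 0.0583), sham 1 (0.0513) or SCI 3 (0.173), and under 4 further settings (0.0523 to 0.0725). The axon injury list lost its call with the strict filter (camera adjusted p = 0.0820).

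In all, edgeR called 8059 of 16627 genes between SCI and naive, 3968 higher and 4091 lower in SCI. With a fold of at least 1.5 as well, 2838 remained, of which 1037 were higher and 1801 lower. The groups did not overlap in 64.1% of genes, where chance gives 10%. The naive group is also the group that stands apart on the first principal component, and the labels give no batch by which the difference could be split.

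The comparison of sham with naive asked how ganglia differed after the operation without cord injury. Genes of ribosomal proteins, oxidative phosphorylation, smooth muscle and skeletal muscle were higher in sham, each as a list, and genes of Schwann cell myelin were lower. With an estimated correlation these list calls were lost (adjusted p = 0.915 for each). The naive libraries stand apart from both other groups on the first principal component, and the labels give no batch. An effect of the operation can therefore not be told apart from a batch that holds only the naive libraries. Pvalb rose from 107 ± 2.80 to 219 ± 17.9 CPM (log2 change 1.04, SE 0.07, edgeR adjusted p = 3.34e-07). Hmga1, a chromatin protein, had a log2 change of 1.31 (SE 0.08), and Pcp4, a calmodulin-binding peptide, 1.01 (SE 0.07). Scn7a, a sodium channel-like protein of glia and neurons, fell from 849 ± 18.4 to 345 ± 9.44 CPM (log2 change -1.30, SE 0.07, edgeR adjusted p = 5.02e-08).

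The 10 genes with the smallest p among those higher in sham than in naive were Lsm4, Hmga1, Timm13, Pvalb, Mrpl43, Hcfc1r1, Anapc15, Selm, Pcp4 and Hypk. Those among the lower included Nfat5, Usp9x, Igf2r, Herc1, Birc6, Mycbp2, Dmxl2, Slc12a2 and Scn7a. Nfat5, an osmotic stress transcription factor, fell from 141 ± 1.61 to 45.1 ± 4.19 CPM, and Birc6 fell from 62.7 ± 3.72 to 18.1 ± 0.889 CPM. Of the 44 further genes with very long coding sequences, 42 were called lower in sham (median log2 change -0.94).

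Of 40 lists, 5 were called between sham and naive, 4 higher and 1 lower, and none of them with an estimated correlation. The skeletal muscle list rose, with 12 of 18 members called higher and none lower (13 adjusted over the list alone) and a median log2 change of 0.94 (camera adjusted p = 0.000497; adjusted p = 0.915 with an estimated correlation). Tnni2 and Acta1 had log2 changes of 1.28 (SE 0.20) and 0.98 (SE 0.15). The ribosomal protein list rose in 38 of 40 members (38 adjusted over the list alone), with a median of 0.66 (camera adjusted p = 8.59e-09; adjusted p = 0.915 with an estimated correlation). Its mean log2 CPM was 7.48, 7.81 and 8.16 in sham libraries 1 to 3 and 7.20 ± 0.00316 in naive, so the sham libraries spread more widely than the naive ones. From sham 1 to 3 the pan-neuronal list fell (9.53, 9.29 and 9.12). The macrophage (3.79, 4.14 and 4.42) and satellite glia lists (7.09, 7.30 and 7.43) rose. Not every list was ordered so, as the lymphocyte list shows (0.285, 0.797 and 0.473). Whether the sham libraries differ in the cells dissected was not tested. The oxidative phosphorylation list rose in 30 of 38 members (32 adjusted over the list alone), with a median of 0.38 (camera adjusted p = 8.59e-09; adjusted p = 0.915 with an estimated correlation). The pericyte and smooth muscle list had 10 of 14 members higher and 1 lower (11 adjusted over the list alone), with a median of 0.59 (camera adjusted p = 0.00767; adjusted p = 0.915 with an estimated correlation). Actg2, smooth muscle actin of the enteric type, rose from 2.00 ± 0.484 to 6.96 ± 0.530 CPM. The Schwann cell myelin list fell, with 16 of 20 members lower and 1 higher (17 adjusted over the list alone) and a median of -0.62 (camera adjusted p = 7.03e-05; adjusted p = 0.915 with an estimated correlation). Fa2h, an enzyme of myelin lipid synthesis, had a log2 change of -0.80 (SE 0.06). Without sham 1, 12 lists were called.

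In all, edgeR called 8407 of 16627 genes between sham and naive, 4102 higher and 4305 lower in sham, and 3243 with a fold of at least 1.5 (1173 higher, 2070 lower). The groups did not overlap in 56.7% of genes, where chance gives 10%.

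**Figure D3:**
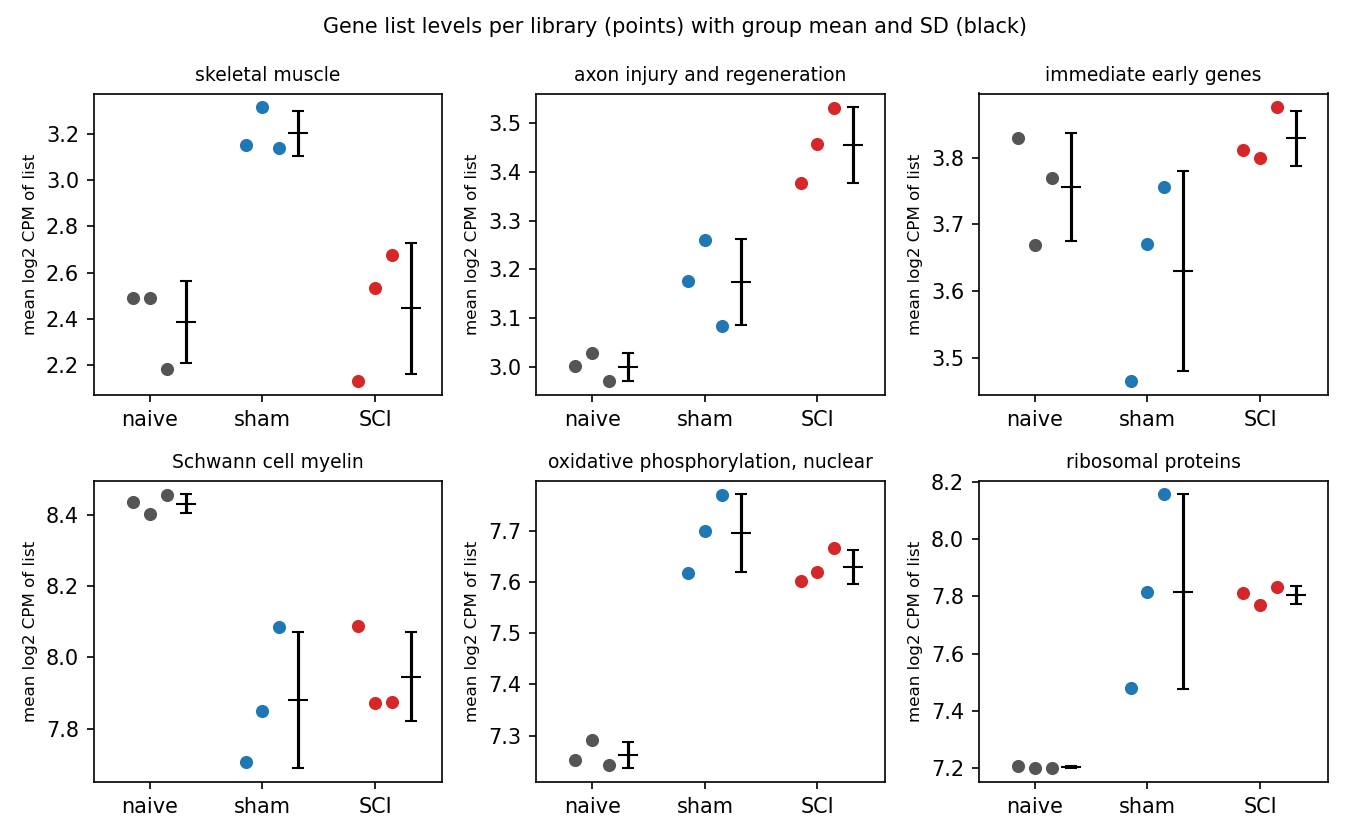
Mean log2 CPM (y axis) of the members of 6 gene lists in each library (points), by group (x axis), with the group mean and SD in black. The skeletal muscle list averages 2.39 in naive, 3.20 in sham and 2.45 in SCI, while the myelin, oxidative phosphorylation and ribosomal lists part the naive libraries from both other groups.

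The changes of SCI and sham against naive were set side by side, both of which use the same naive libraries. Across genes, which are not independent replicates, their log2 changes correlated with r = 0.928, where 40 simulations of unchanged groups that share the naive libraries gave a mean r of 0.458. The covariance was 0.263, against a simulated mean of 0.0156, a difference of 0.247. Both comparisons called 3510 genes higher and 3735 lower, and 0 in opposite directions. Independent lists of these sizes would share 979 and 1059, and unchanged groups shared 0 in the simulations. With 3 naive libraries, no division leaves at least 2 on each side, so part of the overlap may come from the shared libraries. The changes of SCI against naive and SCI against sham correlated with r = 0.0185, where the simulations gave 0.505, and the covariance was 0.00195 against a simulated 0.0178. Those of SCI against sham and sham against naive, which share the sham libraries, correlated with r = -0.354 (simulated -0.535), with a covariance of -0.0398 against a simulated -0.0192. The simulations gave all groups the same spread per gene, while the sham libraries differed more among themselves than the naive or SCI libraries. Differences from the simulated values in the pairs that share SCI or sham libraries can come from that, and no effect is read from them.

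The comparison of SCI with the mean of both control groups asked which genes differed in injured rats from the average of all others. The genes named here were chosen after their values were seen, among those in which all 3 SCI libraries lay outside the range of all 6 control libraries. That separation is therefore the rule of choice and no result of its own. Vip had a log2 change of 2.30 against the controls (edgeR adjusted p = 0.000393), Stac2 1.65 (adjusted p = 0.000101), Fosb 1.57 (adjusted p = 0.00332) and Fos 0.77 (adjusted p = 0.00241). Igf2, a fetal growth factor, had a log2 change of 0.58 (adjusted p = 0.00642), and Reg3a, a lectin related to Reg3b, 2.48 (adjusted p = 0.00455). SCI lay above all controls in 127 genes and below all of them in 108, together 1.41% of genes. Chance would give 2.38% if all 9 libraries were alike, which they are not, since the naive libraries stand apart, so that share is no exact baseline.

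Of 40 lists, 8 were called against both control groups, 3 higher and 5 lower, and none of them with an estimated correlation. The axon injury and regeneration list rose, with 8 of 22 members higher and 2 lower (14 adjusted over the list alone) and a median of 0.20 (camera adjusted p = 0.00133; adjusted p = 0.227 with an estimated correlation). The ribosomal protein and oxidative phosphorylation lists rose, against the mean of the controls, with medians of 0.29 and 0.12 and with 14 of 40 and 11 of 38 members higher (30 and 15 adjusted over the list alone; camera adjusted p = 2.13e-07 and 8.52e-05; adjusted p = 0.891 for each with an estimated correlation). The Schwann cell myelin, cholesterol synthesis, skeletal muscle, GABA and glutamate receptor and potassium channel lists fell, with medians of -0.23, -0.11, -0.36, -0.15 and -0.14 (camera adjusted p = 0.000568, 0.00546, 0.0144, 0.0144 and 0.0254; adjusted p = 0.891 for each with an estimated correlation). Of their members 7 of 20, 6 of 23, 4 of 18, 3 of 24 and 7 of 33 were called lower, and 8, 8, 4, 3 and 7 lower adjusted over the list alone, with 1 cholesterol synthesis gene and 1 skeletal muscle gene called higher. Several of these lists did not lie on the same side of both control groups. Against sham alone, the oxidative phosphorylation and ribosomal lists had negative medians (-0.07 and -0.03) and the Schwann cell myelin list a positive one (0.06, with 17 of 20 members positive), and against naive alone the skeletal muscle list had a median of 0.07. Calls were lost for potassium channels without sham 1 (camera adjusted p = 0.262), SCI 1 (0.0929) or SCI 3 (0.0540), for GABA and glutamate receptors without sham 1 (0.0795) and for skeletal muscle without SCI 1 (0.254), and 15 lists were called without sham 3. EdgeR called 2815 genes in this comparison, 1315 higher and 1500 lower. Leaving out 1 library moved that count from 879 (without SCI 2) to 4934 (without sham 3), with 908 without SCI 3, 1804 and 1861 without naive 1 and naive 2, and 1873 without sham 2. This contrast includes the difference between the naive libraries and both others. Between any of the 3 groups, edgeR called 8057 genes.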

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

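Thinning to equal depth, the muscle covariate and the lists without single members were chosen after seeing the data. Between SCI and naive, all 51 named genes kept their direction and their side of the threshold in the alternatives run for single genes (19, or 18 for Vip, which the strict filter leaves out), and so did all 39 between sham and naive in 19. The fold limit and the adjusted p under 0.1 were run for counts only. Between SCI and sham, 28 of 48 did, 7 passed under some alternative and 15 changed sign under one. The replicate numbers do not pair the libraries: correlations of deviations from the group means ran from -0.0946 to 0.124 over 9 pairs with the same number, 1 above 0.1, and 0 of 9 libraries lay closest to their own number in both other groups. With the replicate block, 0, 7848, 8153, 2477 and 7751 genes were called in SCI against sham, SCI against naive, sham against naive, SCI against both controls and any of the 3 groups, with 7, 8, 6 and 10 lists in the first 4.

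Between SCI and sham, 11 genes were called without the low-count filter, 8 by DESeq2, and 0 to 22 with a library left out. With a fold of at least 1.5, 2838, 3243 and 318 genes remained in SCI against naive, sham against naive and SCI against both controls, which moved the share of higher calls to 36.5%, 36.2% and 34.0%. Leaving out a library gave 6700 to 9180, 7191 to 8630 and 879 to 4934 genes in these comparisons and 6458 to 9488 for any of the 3 groups. For lists it gave 5 to 24, 7 to 10, 5 to 12 and 6 to 15. An estimated correlation left 0 lists in each comparison, and fry called 2 in SCI against sham, 14 in sham against naive and 3 in SCI against both controls. The 2 between SCI and sham were the skeletal muscle and the axon injury lists. At equal depth, 7408 and 7796 genes were called in SCI and sham against naive. The causes were not tested, except that a fold limit removes calls by construction.

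The muscle covariate was added for SCI against sham, where it left 0 genes and 13 lists called. The list's level parts SCI from sham (82.8% of its variance lies between them), so the loss of the muscle list's own change (median -0.0736, with the test turned up) follows by construction. Other changes can be taken up with the group difference, and the values decide nothing about them. The oxidative phosphorylation list had a median of 0.0152. Signs turned for Acta1 (0.079), Tnnt3 (0.047), Kcnip4 (0.069), Cox5a (0.060), Uqcrc1 (0.039), Tac1 (0.23), Calca (0.19), Calcb (0.25), Lpar5 (0.0026), Cd163 (-0.11), Erbb3 (-0.030), Rapgef3 (-0.088), Adcy6 (-0.14) and Creb1 (-0.021). Between sham and naive 92.3% of its variance lies between the groups, and between SCI and naive 2.17%. The covariate gave 7773 genes in SCI against naive, 1041 in sham against naive, 410 in SCI against both controls and 6315 for any of the 3 groups, values seen before its use was limited to SCI against sham. Without sham replicate 3, Trpa1 turned to -0.034 and the potassium channel list had a median of -0.183, which turned to 0.0109 without sham replicate 1. The call of the interferon list in SCI against naive was also lost with upper-quartile scaling, the strict filter, equal depth or only the groups compared, and that of the axon injury list there with the strict filter. The depth of 16724878 counts in sham 2 limits genes near 1 CPM most.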

Other observations

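The tests of depth, of surgery shared by both operated groups, of the position of SCI between the other groups and of the list without Reg3b were written after the values they rest on had been seen. Of 1184 long noncoding RNA genes tested, 362 were called lower and 120 higher in sham against naive, with a median log2 change of -0.23, and 319 lower and 117 higher in SCI against naive, with a median of -0.15. Voltage-gated sodium channel genes had a median of -0.54 in sham and -0.56 in SCI against naive, with 8 and 7 of 12 members called lower and 1 and 2 higher, though the list was not called (camera adjusted p = 0.104 and 0.0944). Calcium channel genes had medians of -0.34 and -0.32, with 10 and 9 of 17 lower and 3 and 2 higher (camera adjusted p = 0.112 and 0.0681). Genes with very long coding sequences lay lower in the same 2 comparisons (medians -0.94 and -0.90). Whether the channel genes follow that pattern was not tested, since gene length was not analysed for these lists. The same holds for the lists called against naive, such as ribosomal proteins, oxidative phosphorylation, Schwann cell myelin and receptors. A bias by transcript length was thus not separated from their changes. Macrophage markers had medians of 0.41 and 0.39, with 11 of 22 higher and 4 lower in both (camera adjusted p = 0.253 and 0.229).

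The naive libraries stand apart from SCI and sham in 8059 and 8407 called genes. Depth is argued against, since 7796 genes were called in sham against naive after all libraries were thinned to equal totals. A loss of very long transcripts in RNA or library preparation is a candidate explanation, prompted by the large proteins among the lowest genes and tested on 44 further genes with very long coding sequences: their median log2 change minus that of all other genes was -0.945 in sham against naive and -0.917 in SCI against naive, with 42 and 41 called lower, where 10000 random lists of like expression had medians down to -0.34. The operation shared by sham and SCI rats would also give the covariance of 0.247 above the simulated value, and cannot be told apart from a batch that holds only the naive libraries, since the labels give none. Both explanations stay open.

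The skeletal muscle list lay lower in SCI than in sham and higher in sham than in naive with a preset correlation, and neither call held with an estimated one (adjusted p = 0.0844 and 0.915). A position of SCI between naive and sham that all genes share is argued against, since the slope over all genes gives 0.138 of the list's mean change (0.114 to 0.224 with a library left out). The list itself lay near its naive level in SCI (mean log2 CPM 2.45 ± 0.281, against 2.39 ± 0.177), on which that slope does not bear. The shared sham libraries already add to that slope (covariance -0.0398, against -0.0192 simulated with no effect). The simulation gave all groups the same spread per gene, and the sham libraries spread more widely, so the part due to shared libraries may be larger. Muscle tissue carried over with the ganglia may account for it, but 32 further muscle genes, none of them in the fixed list, had a median log2 change of -0.23, short of the -0.3 set beforehand as needed but beyond the -0.1 set as counting against it, with 28 of 32 negative. That median lay below all 10000 random lists of like expression (lowest -0.11), and the one in sham against naive, 0.28, above 99.8% of them, so the further genes moved with the fixed list, but by less than the bound, which leaves carry-over open, and a change in muscle-type genes of the ganglia after injury was not tested. Of the 18 list members, 17 lay above 1 CPM in every naive library and 1 is in another of the fixed lists, and Pvalb, Acta1 and Myh1 were the most abundant, at 196, 29.0 and 13.3 CPM in SCI and 219, 49.4 and 22.6 in sham.

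The axon injury and immediate early lists lay higher in SCI than in sham with a preset correlation, and neither call held with an estimated one (adjusted p = 0.0832 and 0.841). Fry called the axon injury list and not the immediate early list. The position of SCI between the other groups is argued against for the axon injury list by its levels. Its mean log2 CPM was 3.00 ± 0.0288 in naive, 3.17 ± 0.0880 in sham and 3.46 ± 0.0775 in SCI, which lay beyond sham. As the slope over all genes is negative, its result was fixed in sign. It gave -0.0898 of that list's mean change (-0.203 to -0.057 with a library left out). For the immediate early list the slope gives 0.0807 (0.0545 to 0.148), which argues only against a position that all genes share. That list lay near its naive level in SCI (3.83 ± 0.0411, against 3.76 ± 0.0808), on which the slope does not bear. A single member with a single high library, Reg3b, is argued against as the source of the camera call of the axon injury list at the preset correlation, since without it the camera adjusted p was 0.000122. The list without Reg3b was not tested with an estimated correlation. The preset test called 7 or more lists in 8 of 10 divisions of these libraries, so the value says only that this call does not need Reg3b. A lasting response of sensory neurons to cord injury may account for the higher axon injury list. The immediate early list was not called between SCI and naive, and its mean was lowest in sham (3.63). Its contrast with sham therefore does not single out such a response. Handling at dissection stays open for the immediate early genes. Neither explanation was tested.

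Other divisions of the libraries were compared with the real one. For 3 libraries against 3 there are 10 divisions, too few for a share under 0.05. The real and the highest other counts of genes were 0 and 1 for SCI against sham (10 of 10 divisions gave as many), 8059 and 0 for SCI against naive (1 of 10), and 8407 and 0 for sham against naive (1 of 10). The counts of lists were 7 and 26 (8 of 10), 8 and 17 (6 of 10) and 5 and 25 (10 of 10), and other divisions with several times the real count of lists point to a structure among the samples. For SCI against both controls, 3 of 100 divisions drawn from 840 gave as many as 2815 genes, a share under 0.05, but all 3 keep the naive libraries together, the highest other gave 5074 and the real one the fewest of them. The share reflects the naive libraries, a structure of the samples, and does not exclude chance for the grouping of SCI against sham libraries. In the count of lists, 82 of 100 gave as many as 8, the highest being 28, so chance is not excluded. For any of the 3 groups, 5 of 100 drawn from 280 gave as many as 8057 genes, the highest being 9428, so chance is not excluded, and the 4 others all keep the naive libraries together.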
